A study of Homo sapiens with 32 samples.

How the data were processed

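The samples were 32 microdissected 10-cell samples of the MCF10A-5E breast epithelial cell line, taken on culture day 10, of which 16 were random samples and 16 pool-and-split controls. Groups and replicate numbers were taken from the sample titles. Samples whose array description shares a leading code were treated as an array set. This gave control set 1 (replicates 1 to 8), control set 2 (replicates 9 to 16), random set 1 (replicates 1 to 9) and random set 2 (replicates 10 to 16). What the codes stand for is not stated in the labels.

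RNA was released with proteinase K, preamplified by poly(A) polymerase chain reaction and labelled with a single dye through aminoallyl groups, per the labels' protocols. The deposited table holds 1 value for each of 20589 Illumina probes and each of the 32 arrays, on a log2 scale judged from the values. The lumi package was used, per the submitters' processing notes, with no version or settings given in the sources used here. Whether the values are a plain log2 or the variance-stabilising transformation that lumi offers remained unknown. That transformation compresses differences among dim probes, so an SD or a difference near the floor may be on a compressed scale. Medians of the arrays lay close together, at 7.81 ± 0.00339 in controls and 7.82 ± 0.00657 in random samples (SD, n = 16 each), but upper values differed between arrays, so the arrays had not been made equal by quantiles. The maximum was 15.66 ± 0.0651 in controls and 15.23 ± 0.149 in random samples. The values were used as deposited. All table columns matched 1 sample each, no 2 arrays held identical values, and the highest correlation between any 2 arrays was 0.918.

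No table of detection p-values was used, so dim probes were handled in 2 ways. For tests, only the 10295 probes with a mean over all samples at or above the median of all probes were kept. For description, a probe was taken as above the floor in an array when it exceeded the array's median by more than 0.5 log2 units, and as high when it exceeded it by at least 2. The floor, the high mark and the counts built on them were chosen after seeing the data. Offsets of 0.3 and 1 were tried as well. Depth on an array means signal over this floor, and probes at the floor carry no order.

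Fluctuation was tested with limma (lmFit and eBayes with a trend) on each probe's absolute deviation from its mean in the array set, multiplied by the square root of n/(n-1) of that set, which is a moderated form of Levene's test. The pair of groups was fitted together, and Benjamini-Hochberg adjusted p-values of 0.05 or less were called. Overall spread was given as the median over probes of the within-set SD ratio, with a two-sided permutation test (100000 resamples) of each sample's mean absolute deviation. Comparisons of array sets with fewer than 10 samples used exact permutation tests, and the values of each measure were adjusted over 8 comparisons. Mean level was tested with limma with array set as a random block (duplicateCorrelation, consensus correlation 0.045), since each set holds 1 group and each group spans 2 sets. A median SD falls with the number of samples, so random set 2 was also compared with all control subsets of its own size, a step added after seeing the data.

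The rule for named features, fixed before the data were examined, took the genes with the largest and smallest SD ratio among called probes that deviated more (or less) in each random set than in each control set. For mean level it took those with the largest and smallest log2 difference among called probes, and it always included a short list of genes. No table used here pairs the probe IDs with gene symbols, so the rule was applied to probe IDs, at most 2 are given in each direction, and the listed genes were not analysed here. For the same reason the gene lists fixed beforehand (pathways, cell type markers and others) could not be tested for fluctuation or co-fluctuation.

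Alternatives set before the data were examined were other filters on dim probes, other scalings of the arrays, deviations on a linear scale, centring on the group, each array set left out, array set as a random block or no block, array noise divided out, squared deviations, an F test of variances, and the replicate number as a block. Added after seeing the data were leaving out each array in turn, leaving out random replicate 16 alone or with replicates 8 and 9, counting replicate 9 in random set 2, random set 2 without replicate 16 as the only random samples, and a filter on probes above the floor in 4 or more samples. After seeing the data, mean level was also compared between each pair of array sets, without a block. Each model was also fitted to 100 splits of the samples into groups of 16, the real one included.

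Both tests were checked on simulated data with 10295 probes. With SDs in the random samples multiplied by 1.5, 2, 3 and 4, the fluctuation test recovered 0%, 8%, 48% and 62% of 50 changed probes each, and false calls made up 10.6% of its calls. With means moved by 0.5, 1, 2 and 3 SDs, the level test recovered 6%, 20%, 92% and 100% of 50 probes each, and 14.2% of its calls were false. In the simulation of fluctuation, therefore, an increase in SD of less than 2-fold was rarely called at this number of arrays. Far fewer probes were changed there than were called in the data, which makes the adjusted threshold stricter. The recovered shares therefore do not carry over directly to the data. Statistics were computed with R 4.3.3, limma 3.58.1 and jsonlite 2.0.0, and figures with Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.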

Results

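Gene expression was measured in 32 samples of MCF10A-5E cells, each holding the RNA of 10 cells. MCF10A is a non-tumorigenic human breast epithelial cell line, and 5E is a clone of it. Grown in an overlay culture with Matrigel, a basement membrane extract, these cells form round, multicellular structures, and the cells sampled here were those attached to the matrix on culture day 10. Cells were cut from frozen sections with a laser, their RNA was amplified by a poly(A) polymerase chain reaction, and the product was hybridised to 1-colour Illumina arrays. The labels divide the samples into 16 random samples, each microdissected on its own, and 16 pool-and-split controls, in which RNA from a larger number of microdissected cells was divided into 10-cell equivalents before amplification. The controls therefore carry the variation of amplification and hybridisation, and the random samples carry that variation together with differences between cells and between extractions. The array labels place the samples in 4 array sets, each of 1 group: control set 1 (replicates 1 to 8), control set 2 (replicates 9 to 16), random set 1 (replicates 1 to 9) and random set 2 (replicates 10 to 16). The labels do not say that the samples came from separate cultures, so the p-values below measure only the spread between these samples, part of which may be technical. Between controls split from the same pool that spread is technical, so the controls are not independent samples of cells. A shift in level that belongs to a pool cannot be told apart from a difference between the groups. The files do not pair the probe IDs with gene names, so probes are given by their IDs.

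The table held 20589 probes on a log2 scale. A probe was counted as above the floor in a sample when it exceeded that array's median by more than 0.5 log2 units. By this measure 1559 probes, or 7.57%, were above the floor in all 32 samples, 6924 in some of them, and 12106, or 58.8%, in none. More probes were above the floor in all 16 controls (2335) than in all 16 random samples (1729). Each control had 4346 ± 101 probes above the floor (SD, n = 16), and each random sample 4520.5 ± 470 (SD, n = 16), a difference that did not pass a two-sided permutation test (p = 0.159, adjusted p = 0.212 over 8 comparisons of this measure). The result depended on the floor and on the samples. With a floor 1 log2 unit above the median the difference, random minus control, was 204.7 probes (permutation p = 0.00548), compared with 174.2 in the main setting. With a floor 0.3 log2 units above the median it was 154.4 (permutation p = 0.305), and without random replicate 16 it was 209.3 (permutation p = 0.0888). With random set 2 without replicate 16 as the only random samples it was 612.2 (permutation p = 2.0e-05). The spread of these counts between samples was wider in the random group, from 3820 to 5086, than in the controls, from 4125 to 4474. The random sets differed in this count, with 4287 ± 401 probes in random set 1 (SD, n = 9) and 4821 ± 388 in random set 2 (SD, n = 7; two-sided exact permutation test, p = 0.0221, adjusted p = 0.0354). Random set 2 exceeded control set 1, at 4429 ± 31.3 (SD, n = 8; exact p = 0.0137, adjusted p = 0.0274), and control set 2, at 4264 ± 72.1 (SD, n = 8; exact p = 0.00404, adjusted p = 0.0108). The control sets differed from each other as well (exact p = 0.000155, adjusted p = 0.000622). The number of arrays limits the precision of all values.

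The comparison the study was designed for sets the fluctuation of expression between random samples against that between pool-and-split controls. Over the 10295 probes tested, random samples spread more than controls. The median within-set SD was 0.394 log2 units in random samples and 0.267 in controls. The median over probes of the SD ratio, random over control, was 1.45, with quartiles of 1.04 and 2.10, and the ratio was above 1 for 77.4% of probes. Per sample, the mean absolute deviation from the array set's mean was 0.348 ± 0.0779 log2 units in random samples (SD, n = 16) and 0.265 ± 0.00892 in controls (SD, n = 16), a ratio of 1.31 (two-sided permutation test, p = 0.00031, adjusted p = 0.000827 over 8 comparisons).

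The larger spread was unevenly divided between the random sets. Random set 1 deviated by 0.394 ± 0.046 log2 units per sample (SD, n = 9), more than control set 1 at 0.258 ± 0.00635 (SD, n = 8) and control set 2 at 0.272 ± 0.00424 (SD, n = 8), with an exact permutation p of 0.000123 and an adjusted p of 0.000494 for each. The control sets differed from each other as well, by less (exact permutation p = 0.000777, adjusted p = 0.00155). A small p between 2 array sets therefore does not by itself separate group from array set. Random set 2 deviated by 0.288 ± 0.0706 (SD, n = 7) and was not separated from control set 1 (exact p = 0.244, adjusted p = 0.325) or control set 2 (exact p = 0.836, adjusted p = 0.836). Within random set 2, replicate 16 deviated by 0.442, while the other samples lay between 0.237 and 0.297. The other samples of random set 2 deviated by 0.262 ± 0.0205 (SD, n = 6), against 0.265 in all controls (two-sided permutation test, p = 0.647, adjusted p = 0.739). These deviations were still taken from the mean of all 7 arrays, replicate 16 included, so they are not the spread without it. With random set 2 without replicate 16 as the only random samples, the permutation p was 0.122. In that setting the median SD ratio was 0.941, below 1, although a median SD falls with fewer samples. Set against control subsets of the same size, the median SD without replicate 16, 0.249 log2 units, lay above the highest of the 56 subsets (0.230), with a ratio of 1.12 to their mean. With all 7 arrays of random set 2 the median SD was 0.287, above the highest control subset (0.238), with a ratio of 1.23.

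**Figure D1:**
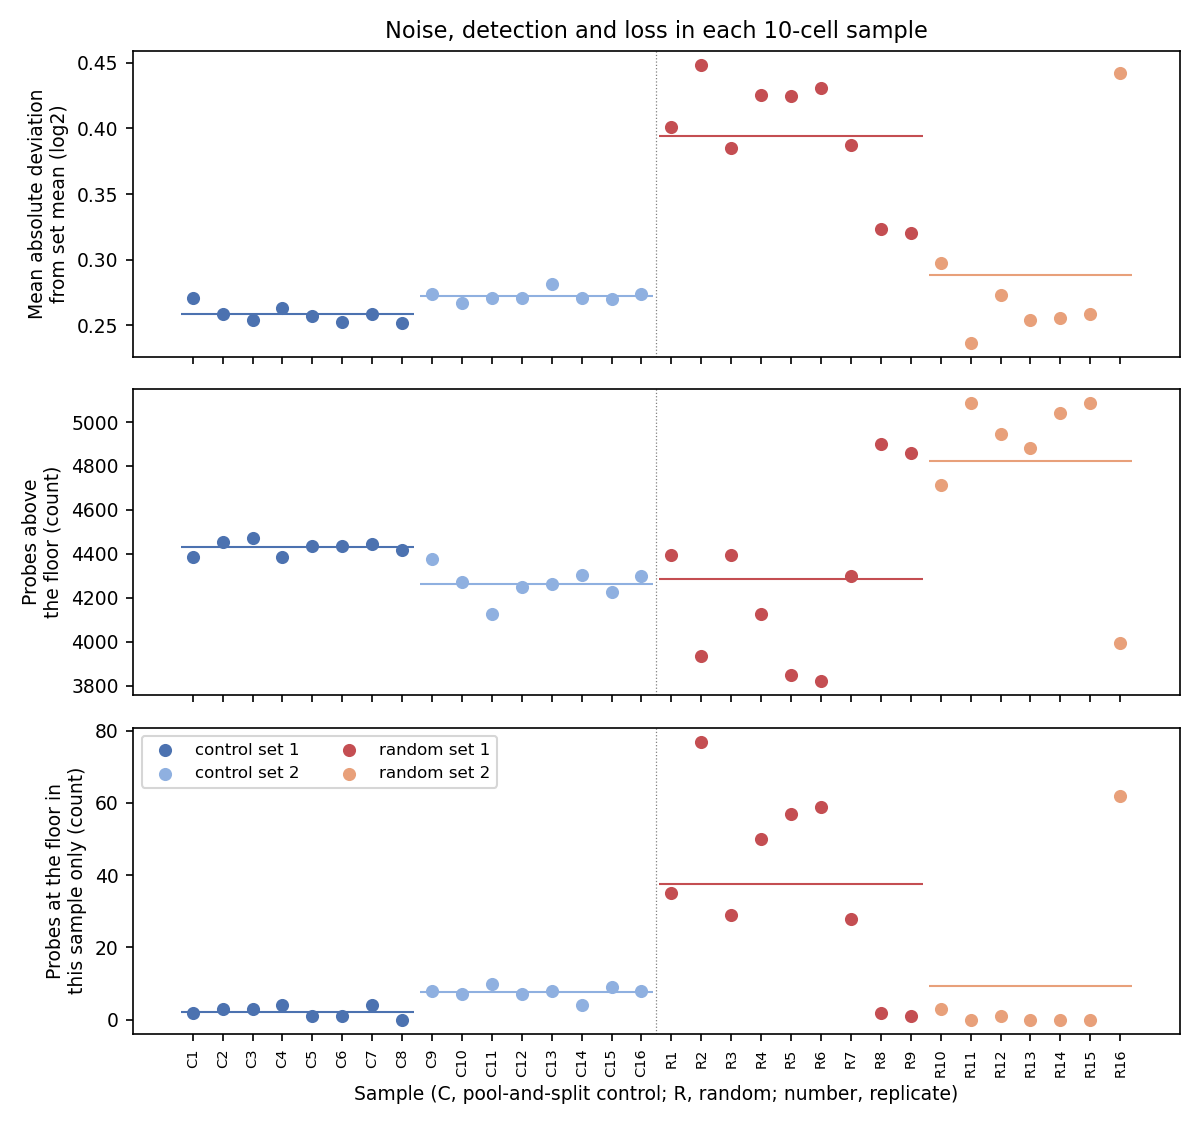
Each point is 1 sample (C, control; R, random), coloured by array set, with a line at the set's mean. The panels give the mean absolute deviation from the set mean (log2 units, top), the number of probes above the floor (middle) and the number of probes at the floor in that sample and above it in all other 31 (bottom); random replicates 1 to 7 and 16 show the largest values in the top and bottom panels, with replicate 16 at 0.442 and 62.

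Samples also differed in how many otherwise detected transcripts were missing. A probe at the floor in 1 sample and above it in the other 31 was counted as a dropout of that sample. Random samples had 25.25 ± 27.9 dropouts (SD, n = 16) and controls 4.94 ± 3.19 (SD, n = 16; two-sided permutation test, p = 0.0060, adjusted p = 0.0103 over 8 comparisons). Random set 1, at 37.6 ± 25.8 (SD, n = 9), exceeded control set 1 (exact permutation p = 0.00193, adjusted p = 0.00773) and control set 2 (exact permutation p = 0.00646, adjusted p = 0.0103). Random set 2 was not separated from control set 1 (exact permutation p = 0.829, adjusted p = 0.947) or control set 2 (exact permutation p = 0.999, adjusted p = 0.999). Without replicate 16 it had fewer dropouts than controls, 0.667 ± 1.21 (SD, n = 6; permutation p = 0.00526, adjusted p = 0.0103). The control sets differed from each other, at 2.25 ± 1.49 and 7.62 ± 1.77 (SD, n = 8 each; exact permutation p = 0.000466, adjusted p = 0.00373). The count ranged from 0 to 77 in random samples and from 0 to 10 in controls. Random replicates 1 to 7 had 35, 77, 29, 50, 57, 59 and 28 dropouts, and replicate 16 had 62. The remaining random samples, replicates 8 to 15, had between 0 and 3. The opposite case, a probe at least 2 log2 units above the array median in 1 sample and at the floor in the other 31, was rare in both groups, with 2.38 ± 2.58 such probes in random samples (SD, n = 16) and 1.69 ± 0.873 in controls (SD, n = 16; permutation p = 0.372, adjusted p = 0.496).

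The spread was also compared by expression level. The tested probes were divided into 4 bins of equal size by their mean over all 32 samples. From the dimmest bin (means of 7.83 to 7.90 log2 units) to the brightest (9.27 to 15.38), the median SD ratio was 1.69, 1.5, 1.36 and 1.40. The means of the 2 dimmer bins lie below the floor, and no test of a trend with level was run. In the dimmest bin the median SDs were 0.0520 log2 units in random samples and 0.0264 in controls, so its ratio largely compares variation at the floor. In the second dimmest they were 0.302 and 0.194, so its ratio may also reflect probes above the floor in only some samples. In random set 1 alone the median SD ratio was 1.71, 1.51, 1.5 and 1.59, and in random set 2 it was 1.19, 1.17, 1.08 and 1.01. In random set 2 without replicate 16, the median SD over that of control subsets of 6 arrays was 1.22, 1.45, 0.978 and 0.906 in the same order. In the brightest bin the median SD itself was 0.365 log2 units, under the lowest of the 56 control subsets at 0.366, and in the second dimmest bin it was 0.192, above the highest control subset at 0.143.

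**Figure D2:**
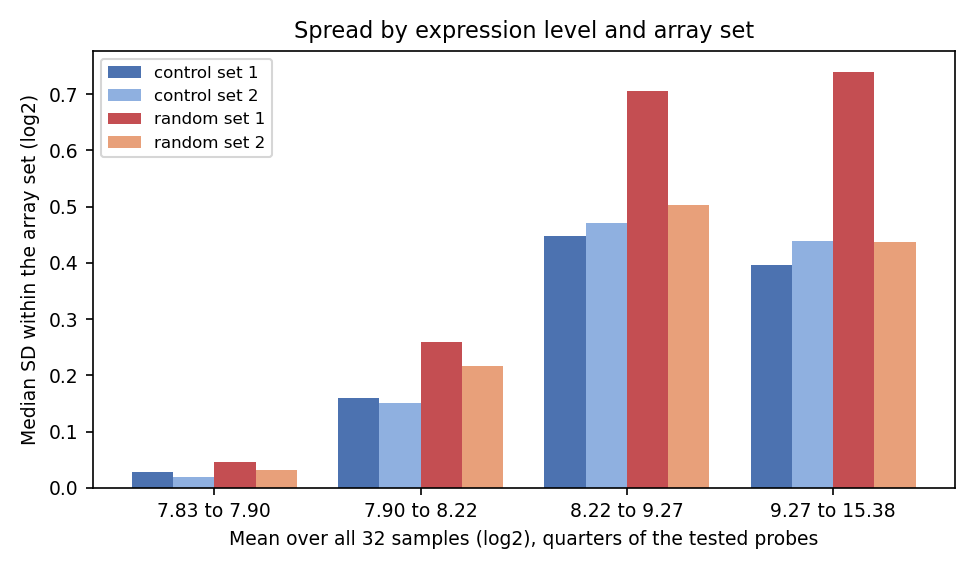
Bars give the median within-set SD (log2 units, axis from 0) of the tested probes in each array set, for the 4 bins of probes by mean expression over all 32 samples (log2). Random set 1 has the highest bar in each bin, and random set 2 lies close to the control sets in the brightest bin, with a median SD ratio of 1.01.

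Single probes were tested for larger or smaller fluctuation with limma on absolute deviations from the set mean, with Benjamini-Hochberg adjustment. Fluctuation was larger in random samples for 1354 probes, 13.2% of those tested, and smaller for 161, or 1.56%. This fit had no term for array set, and with array set as a random block both counts were 0. Of the 1354 probes, 1275 deviated more in each random set than in each control set. That ordering was met by 3893 of all tested probes, or 37.8%, where chance orderings of 4 sets would give 16.7%. The 1354 probes were called on these same deviations, so their ordering is no independent support. Probes that the controls did not detect made up most of the calls: 816 of the 1354 (60.3%) were at the floor in all controls, compared with 31.1% of all tested probes. Of these 816 probes, 427 rose above the floor in at least 1 random sample, and 389 did so in no sample, so their SDs differed only within the floor. Among the other calls, 175 were above the floor in all controls, 89 of them in all 32 samples and 86 missing in 1 or more random samples, and 363 were above the floor in some controls only. A random SD of at least 0.5 log2 units was found for 481 of the called probes. The share of probes called as more variable was 16.9%, 18.4%, 10.9% and 6.33% from the dimmest to the brightest bin.

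The probes named for fluctuation were at the floor in every sample of one group, where an SD reflects only noise at the floor, so their SDs are given without a ratio or a rank. ILMN_5307 was above the floor in 2 of 16 random samples, reaching 11.15 log2 units, and in 0 of 16 controls, and its within-set SD was 1.1 in random samples and 0.0082 in controls. Its mean absolute deviation was higher in random samples by 0.679 ± 0.204 log2 units (SE; limma adjusted p = 0.0255), and this call was lost without random replicate 3 (difference 0.40, limma adjusted p = 0.104) or random replicate 5 (difference 0.423, limma adjusted p = 0.105). The excess lay in random set 1, and without that set the difference was 0.0103 (limma adjusted p = 0.216). ILMN_2840 was above the floor in 4 of 16 random samples, reaching 10.78, and in 0 of 16 controls. Its SD was 0.984 in random samples and 0.011 in controls, and its deviation was higher by 0.748 ± 0.157 (SE; limma adjusted p = 0.00405). That difference was 1.22 without random set 1 and 0.377 without random set 2, and passed in both. The call was lost without control set 1 (limma adjusted p = 0.0702) or control set 2 (limma adjusted p = 0.0734), with a difference of 0.748 in each.

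In the opposite direction, 146 of the 161 probes with smaller fluctuation in random samples deviated less in each random set than in each control set. That ordering was met by 665 of all tested probes, or 6.46%, where chance orderings would give 16.7%. The 161 probes, too, were called on the same deviations. Of the 161 probes, 102 were at the floor in all random samples, 10 were above the floor in no sample, and 86 had a control SD of at least 0.5 log2 units. ILMN_21070 was above the floor in 2 of 16 controls, reaching 10.92, and in 0 of 16 random samples, with SDs of 1.11 in controls and 0.0126 in random samples. Its difference in mean absolute deviation, random minus control, was -0.725 ± 0.201 (SE; limma adjusted p = 0.0175), and the call was lost without control replicate 2 (difference -0.385, limma adjusted p = 0.109) or control replicate 13 (difference -0.387, limma adjusted p = 0.113). ILMN_975 was above the floor in 3 of 16 controls, reaching 11.35, and in 0 of 16 random samples, with SDs of 1.11 and 0.0236. Its difference was -0.761 ± 0.193 (SE; limma adjusted p = 0.0104), and the call was lost without control replicate 15 (difference -0.476, limma adjusted p = 0.0726). Without control replicate 8 the difference was -0.490 (limma adjusted p = 0.0238).

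These counts depended on the array sets. With array set as a random block, limma called 0 probes in either direction, against 1503 higher and 190 lower at an unadjusted p under 0.05 in that fit. None of the 4 probes named for fluctuation passed with that block, although their differences moved little. The difference in mean absolute deviation was 0.644 log2 units for ILMN_5307, 0.773 for ILMN_2840, -0.725 for ILMN_21070 and -0.760 for ILMN_975 in that fit. Without random set 1 the counts were 742 higher and 33 lower, and without random set 2 they were 2760 and 212. Without control set 1 they were 50 and 71, and without control set 2 they were 52 and 94.

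Mean log2 expression was also compared between the groups. The controls average a larger number of cells before the log2 is taken. A transcript that varies between random samples therefore has a lower mean of log2 values at the same average. For this reason the calls do not by themselves show whether the average profiles agree. This effect lowers the mean in random samples, so it could add to lower calls or hide higher ones. It would not by itself give a higher mean there. Expression was higher in random samples for 1235 of the 10295 probes and lower for 339, by limma with array set as a random block and Benjamini-Hochberg adjustment, and the median difference over all tested probes was 0.0405 log2 units. After quantile normalization 560 probes were higher and 369 lower, which moved the share of higher calls from 78.5% to 60.3%. The counts were 590 and 228 without control set 1, 355 and 98 without control set 2, and 2779 and 934 without random set 2. A difference of at least 1 log2 unit was found for 101 of the higher and 45 of the lower probes. In 1201 of the 1235 probes each random set lay above each control set, and in 334 of the 339 each lay below. These probes were called on the same values, so their ordering is no independent support. Of the higher probes, 527 were at the floor in all controls and 404 were above the floor in all 32 samples. Of the lower probes, 76 were at the floor in all random samples and 198 were above the floor in all 32. In the brightest bin 417 probes were higher and 242 lower, while in the other 3 bins, from the dimmest, 279, 240 and 299 were higher and 32, 42 and 23 lower.

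ILMN_22503 had the largest rise, from 9.34 ± 0.298 in controls to 12.15 ± 0.679 in random samples (SD, n = 16 each), a log2 difference of 2.81 ± 0.213 (SE; limma adjusted p = 1.40e-11). ILMN_12818 rose from 8.91 ± 0.215 to 11.62 ± 0.441 (SD, n = 16 each), a log2 difference of 2.71 ± 0.146 (SE; limma adjusted p = 5.77e-15). Both probes were above the floor in all 32 samples. ILMN_12248 was lower in random samples, at 10.40 ± 1.80 compared with 12.47 ± 0.472 in controls (SD, n = 16 each), a log2 difference of -2.05 ± 0.528 (SE; limma adjusted p = 0.00688), and was above the floor in 12 of 16 random samples and 16 of 16 controls. That call was lost without control set 1 (difference -2.20, limma adjusted p = 0.0644) or control set 2 (difference -1.91, limma adjusted p = 0.171), with differences close to the main one. ILMN_11426 was above the floor in 3 of 16 random samples and 15 of 16 controls, at 8.17 ± 1.01 and 10.13 ± 1.11 (SD, n = 16 each). Its log2 difference was -1.95 ± 0.402 (SE; limma adjusted p = 0.000801), and the call was lost without control set 2 (difference -1.03, limma adjusted p = 0.256) or random set 1 (difference -1.51, limma adjusted p = 0.0514). It was lost as well with random set 2 without replicate 16 as the only random samples (difference -1.55, limma adjusted p = 0.0759). Samples at the floor give no exact level, so the fitted differences of ILMN_12248 and ILMN_11426 are not exact sizes. The directions of these 4 probes were the same under both other scalings tried.

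**Figure D3:**
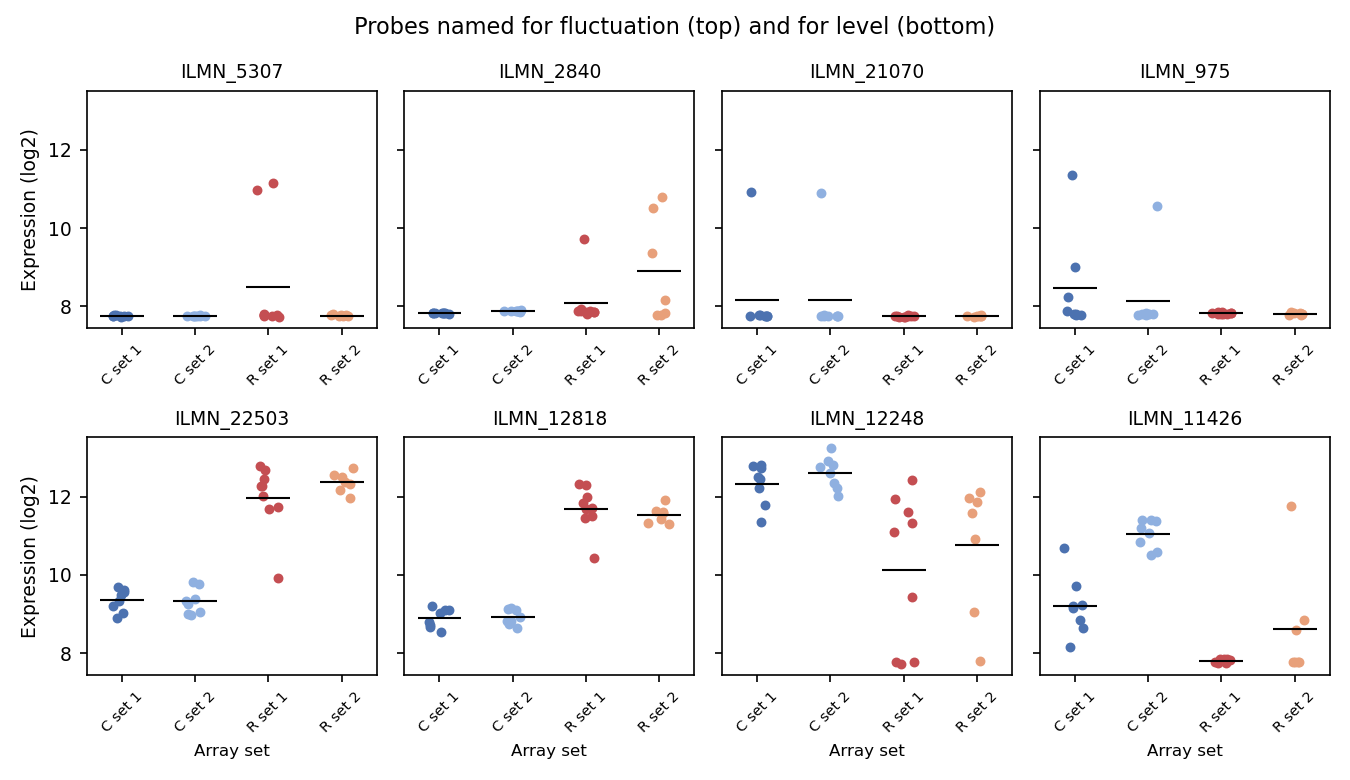
Expression (log2, one axis range for all panels) of the 4 probes named for fluctuation (top) and the 4 named for mean level (bottom), with 1 point per sample by array set (C, control; R, random) and a line at the set's mean. ILMN_5307 stands above the floor in 2 random samples and ILMN_21070 in 2 controls, while ILMN_12818 is higher in the random samples, at 11.62 on average compared with 8.91.

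Some probes had both larger fluctuation and a higher mean in random samples. Of the 1354 probes with larger fluctuation in random samples, 380 also had a higher mean there and 20 a lower one, where independent lists would share 162 and 44.6 probes. A further 954 had no call for mean level. A call for mean level was made for 29.5% of the probes with larger fluctuation and for 15.3% of all tested probes. Both tests used the same samples, so part of this overlap may come from shared values. For a probe at the floor in all controls, as 816 of the 1354 were, a rise in some random samples lifts spread and mean together. Such a probe can hardly have a lower mean. The comparison with independent lists therefore does not show a link beyond this.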

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

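The tests of transcript loss, of cell-to-cell differences, of detection, of the wrong set for replicate 9, of its hybridisation and of the swap, and the measures of floor and dropout, were chosen only after the results had been seen. The tests over all tested probes were then split by expression level, also after their values were seen.

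Random replicate 16 lay far from the other samples of random set 2 in 4 measures. Its mean absolute deviation was 0.442 log2 units (the others 0.237 to 0.297), it had 3994 probes above the floor (the others 4714 to 5086), 5 probes high in it alone (the others 0 to 1), and 62 dropouts (the others 0 to 3). Chance puts about 1 in 20 groups past this limit, and 4 measures in 4 array sets were looked at, in 16 combinations that are not independent. Replicates 8 and 9 of random set 1 had few dropouts, 2 and 1, and no sample of that set passed the same limit. A score from 8062 dim probes, which measures how far an array's dim values resemble random replicates 1 to 8 rather than 10 to 15, was -0.131 for replicate 9, inside the range of replicates 10 to 15 (-0.163 to -0.0988) and below that of replicates 1 to 8 (0.199 to 0.340), but 4 of the 16 controls also lay inside the former range. It was 0.00668 for replicate 16, between these ranges. The score rests on probes at the floor, and the dropouts of replicate 16 lie within the range of replicates 1 to 8 (2 to 77), so a swap of replicates 9 and 16, and hybridisation of replicate 9 with the arrays of random set 2, stay open. The 62 dropouts of replicate 16, with at most 10 in any control, are consistent with loss of transcripts in it.

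The random sets also differed in spread, with a mean absolute deviation 1.37 times as large in random set 1 as in random set 2 (two-sided exact permutation test, p = 0.00446, n = 9 and 7, adjusted p = 0.00713). Counting replicate 9 in random set 2 left the overall SD ratio at 1.42, which argues against a wrongly placed array as the whole cause of the larger spread in random samples.

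For the brighter 2 of the 4 expression bins of the tested probes, the size-matched ratio of median SDs in random set 2 without replicate 16 was 0.936, compared with 1.57 to 1.68 in random set 1. This is consistent with loss of transcripts in some of the random samples as a source of the larger spread of bright probes. Cell-to-cell differences that raise the spread in every random sample cannot be told apart from no such differences. The ratio was at most 0.977 with a further array left out, but these arrays also had more probes above the floor than any control, and a better yield may have lowered their technical spread below that of the controls.

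For the dimmer 2 bins the same ratio was 1.86, and 1.83 to 1.90 with a further array left out, compared with 1.77 to 1.97 in random set 1. By this ratio the random samples with few dropouts spread about as much as random set 1. This median lies where SDs rise steeply with expression, however, and the ratios of random set 2 without replicate 16 within each of these bins were 1.22 and 1.45. In the dimmest bin the median SD, 0.0266 log2 units, lay inside the range of the control subsets (0.0173 to 0.0270), and only the second dimmest exceeded it. Loss in some samples therefore stays open as the cause for the dim probes. Random replicates 10 to 15 had at least 4714 probes above the floor and no control more than 4474, so better detection of dim transcripts is a candidate explanation. Cell-to-cell differences, with a ratio of up to 1.90, stay open beside it, because detection and group changed together. Over all tested probes the ratio was 1.12, and the same tests on it decided neither explanation.

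Chance can be excluded as the source of the calls only against random splits that ignore the array sets. Of 100 splits into 16 and 16 samples, 1, the real one, gave as many probes with larger fluctuation (1354; the highest other had 0), and 1 gave as many with smaller fluctuation (161; highest other 0). For mean level, 1 of 100 gave as many higher probes (1235; highest other 1), and 1 as many lower (339; highest other 1). The 2 splits with 1 control set and 1 random set on each side gave 102 and 109 fluctuation calls without a block, against 1515 in the real one. With array set as a random block, limma called 0 probes for fluctuation in the real split and in both of these (1693, 499 and 417 at an unadjusted p under 0.05), so that count does not tell the splits apart. For mean level, limma was fitted to each pair of array sets. Between sets of the same group the count was 157 for the control sets and 0 for the random sets. The counts between a control set and a random set were 1215, 779, 1931 and 1316. This argues against set differences of the size seen within a group as the whole cause of the level calls, although the control sets did differ. Each group has only 1 such pair, however. A pool or batch shift shared by both sets of a group would not show in it, so a cause of that kind stays open.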

How the results depend on the processing

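Array set and the choice of test moved the counts of fluctuation calls most, and the cause was not tested. Some of these settings also used fewer samples or probes, which by itself can change a count. The main counts were 1354 higher and 161 lower. With array set as a random block both were 0 (limma, 1503 and 190 at an unadjusted p under 0.05). With squared deviations they were 8 and 0 (limma, 1975 and 133 at an unadjusted p under 0.05), and with an F test of variances, which is sensitive to single extreme values, 2961 and 498. They were 50 and 71 without control set 1, 52 and 94 without control set 2, and 742 and 33 without random set 1. Without random set 2, 2760 were higher. With random set 2 without replicate 16 as the only random samples they were 593 and 23. With only the probes whose mean reached the 0.75 quantile of all probes they were 385 and 25, and with probes above the floor in 4 or more samples 707 and 80. Dividing out array noise gave 540 higher, 535 of them shared with the main list, and 200 lower (1738 and 850 at an unadjusted p under 0.05), and quantile normalization gave 254 lower. The overall spread ratio of 1.45 fell to 1.09 without random set 1 (permutation p = 0.213). It turned to 0.941 with random set 2 without replicate 16 (p = 0.122), where the smaller set lowers a median SD. For mean level, the 1235 higher calls became 804 with the probes above the 0.75 quantile, 560 with quantile normalization, 590 without control set 1, 355 without control set 2 and 2779 without random set 2. The 339 lower calls became 546 with no block, 98 without control set 2 and 934 without random set 2. The difference in probes above the floor, 174.2, was 154.4 with an offset of 0.3 (permutation p = 0.305) and 204.7 with an offset of 1 (permutation p = 0.00548). It was 612.2 with random set 2 without replicate 16 (permutation p = 2.0e-05). In that setting the difference in probes high in 1 sample turned from 0.688 to -1.35 (p = 0.0126) and that in dropouts from 20.3 to -13.5 (p = 0.00426), counted over fewer samples.

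With each of the 32 arrays left out in turn, the counts ranged from 1159 to 1595 for larger and 128 to 184 for smaller fluctuation, 1094 to 1344 for higher and 297 to 371 for lower mean level, and the spread ratio from 1.41 to 1.48. Without random replicate 16 the differences were 209.3 probes above the floor, 0.512 probes high in 1 sample and 20.5 dropouts. Over the other alternatives, ILMN_22503 and ILMN_12818 kept their calls in 14 of 14, while ILMN_12248 lost its call in 2 of 14, ILMN_11426 in 3 of 14, ILMN_5307 in 6 of 17, ILMN_2840 in 4 of 18, ILMN_21070 in 6 of 17 and ILMN_975 in 5 of 17. None of these 8 changed sign.

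Replicate numbers did not pair the samples. Same-numbered samples had a median correlation of 0.020 between their deviations (-0.032 to 0.0485), with 0 of 16 pairs over 0.1. With the replicate number as a block the counts were 1217 and 147 for fluctuation, and 1701 and 512 for mean level. The 2 planned results on gene lists (larger fluctuation, and larger co-fluctuation, in random samples) were not run, because no table used here pairs probe IDs with genes. Signal over background limits what can be seen: 389 of the 1354 probes with larger fluctuation were above the floor in no sample.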

Other observations

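The test of shared movement below was chosen only after the main results had been seen. It asked whether probe pairs that move together in random set 1 also do so in random set 2, as transcripts that vary together between cells would. Over the 3311450 pairs of the 2574 brightest probes, the correlations of the pairs in random set 1 and in random set 2 were themselves correlated at 0.0292, across pairs that are not independent. The highest value with probe names permuted was 0.0020 (p = 0.005, the smallest these permutations can give). The 2 control sets, which hold split pools, were correlated at 0.0412, and a random with a control set at 0.0109 to 0.0208. With 1 array left out the values ranged from 0.0132 to 0.0308 for the random sets and from 0.0294 to 0.0436 for the control sets. Without replicate 16 the value of the random sets was 0.0153, below the 0.0168 and 0.0193 of the control sets with random set 2 without that replicate. With all arrays the value of the random sets was below that of the control sets, but the ranges with 1 array left out overlapped. The value between split pools shows that shared movement can arise without differences between cells. It does not show the source of the shared movement in the random sets. Whether transcripts that vary together between cells contribute to it was therefore not decided.

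With random set 2 without replicate 16 as the only random samples, a setting chosen after seeing the data, 593 probes had larger fluctuation than in all controls, and 371 of them were among the 1354 called with all samples. Both fits used the same controls and random replicates 10 to 15, so this overlap is not a replication. Of the 593 probes, 474 were at the floor in all controls, as were 31.1% of all tested probes. Among the 593, 203 were above the floor in no control and in none of the random replicates 10 to 15, and 21 were above the floor in all controls. The mean was higher in random replicates 10 to 15 than in controls for 576, and 94 were called higher in the main level fit. Larger fluctuation and better detection in these arrays cannot be told apart here.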
